A study of Mus musculus with 5 samples.

How the data were processed

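RNA from organoids of mouse fallopian tube epithelium was sequenced in 5 libraries, 1 per genotype: normal, RPM, RPMN, RPMP and RPMNP. Per the labels' protocols, total RNA was extracted from the cultures with a Qiagen RNeasy Plus kit, strand-marking libraries were made with the NEBNext Ultra II Directional kit, and pooled libraries were read as 50 bp paired ends on an Illumina NextSeq instrument. The labels give conditioned medium as the treatment of all 5. The build was GRCm39, per the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here.

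The authors deposited 1 table of TPM values per library, which are read numbers divided by transcript length and scaled to a fixed total within the library. The TPM values of each deposited table summed to 1000000 over 25668 gene symbols, of which 8269 were at 0 in all 5 libraries. TPM keeps no depth, so the number of reads behind a value is unknown, no counting interval can be given, and a listed 0 cannot be given an upper limit. Scaling to a fixed total also means that a few very abundant genes lower all others in the same library. The 10 most abundant genes that are not mitochondrially encoded took 10.6% of the TPM in normal and 5.14% to 5.55% in the transformed libraries. Genes with near-identical copies, such as histone, MHC class I, Serpina1, Sprr2 and Ly49 family genes, share reads in a way that depends on the counting, which is not known, and their values are less certain.

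From these tables, log2(TPM + 1) was computed, and 12943 genes with at least 1 TPM in 1 or more of the 5 libraries were kept. Log2 ratios between libraries were differences on this scale, and genes were counted as apart from an absolute log2 ratio of 1. A gene was called higher or lower in all 4 transformed libraries when each passed against the normal library, and with an added knockout when both contrasts passed on the same side. With 1 library per group no test was run and no p-value, standard error or number of significant genes is given. For the 4 ratios that share the normal library, 100 data sets were simulated in which it was unchanged, from each gene's mean over all 5 libraries and its spread over the 4 transformed ones. Correlations between contrasts are across genes, and the SD of the Pearson correlations comes from 200 resamplings of whole chromosomes.

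A set of 40 gene lists was written before the data were examined, with 870 memberships of which 862 were found under the listed symbols, 1 of them (Car9, written as Ca9) by a synonym. Symbols such as Xist, Aldoa, Ddit3 and H19 were not listed. For the 37 lists with at least 3 members after the filter, the median log2 ratio was placed among 10000 random lists of the same size, drawn from 20 bins of mean log2(TPM + 1). A list stands apart below the 2.5 or above the 97.5 percentile. The fibroblast, endothelial and sex chromosome lists had too few measured members for a median.

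Named genes followed a rule written in advance. It names the 5 engineered genes first. For the transformed libraries it takes the 12 highest and 12 lowest RPM ratios among genes 2-fold apart in all 4 with at least 10 TPM in RPM or normal. For Nf1 and for Pten it takes the 10 highest and 10 lowest genes by the smaller of both ratios, with at least 10 TPM in 1 transformed library. For each transformed library it takes up to 5 genes per direction by the smallest ratio to the other 3. From each list it takes up to 4 members with the largest ratios and up to 2 that went the other way. For Nf1 and Pten the list members were ranked on the mean of both contrasts. Predicted genes, RIKEN clones, mitochondrial and pseudogene symbols were passed over in the genome-wide parts of the rule.

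The reference annotation at hand is of the older build GRCm38, so no coordinates are given. It was used to learn which genes share a chromosome and neighbour each other (98.7% of the filtered genes had a chromosome) and for transcript length and GC content. Chromosomes are named by a gene on them. Chromosome medians used 9998 genes with a mean of at least 5 TPM and a known chromosome, split into 10 blocks of neighbouring genes per chromosome.

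The alternatives tried were pseudocounts of 0.1 and 5 TPM, no filter on low values, a filter of 5 TPM, and rescaling by the median ratio, without mitochondrial and ribosomal protein genes, or without the top 100 genes. After seeing the data, 3 more were added: leaving out the chromosome that carries Rb1, leaving out those that carry Cdk6 and Dhfr, and centring the ratios per chromosome. The counting code was tested on simulated data with 200 of 12943 genes changed 4-fold. It recovered 98.5% of them with 0 unchanged genes for the transformed comparison, and 99.5% with 2 unchanged genes for the Nf1 comparison. Of 200 simulated lists without change, 4.5% stood apart, and all of 50 lists with 10 of 20 members changed did so. All simulated genes had independent noise of the same SD (0.264 on the log2 scale), and changed genes were drawn from the higher expressed ones. These rates check the code and are not error rates for the real libraries, where list members vary together. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.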

Results

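Organoids of mouse fallopian tube epithelium, 3-dimensional cultures grown from the lining of the tube that carries the egg to the uterus, were profiled by RNA sequencing in 5 genotypes with 1 library each. The normal library came from an animal with loxP-flanked Rb1 and Trp53 alleles and a silent Myc transgene, none of them recombined per the labels. The other 4 libraries were labelled as transformed. By these labels RPM has Rb1 and Trp53 knocked out and Myc overexpressed, RPMN has Nf1 knocked out in addition, RPMP has Pten knocked out in addition, and RPMNP has both. Each library lists length-corrected transcript abundance (TPM) for 25668 gene symbols, and TPM values keep no record of sequencing depth. Between 11325 genes in RPMP and 12036 genes in normal had at least 1 TPM. As each genotype has 1 library, no difference below has a replicate check, and the 4 transformed genotypes are not replicates of each other. All comparisons therefore describe these libraries. They are stated as TPM, as log2 ratios of TPM + 1 (which understate the change of genes with low values) and as counts of genes at least 2-fold apart on that scale, over the 12943 genes with at least 1 TPM in 1 or more libraries.

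The engineered genes were examined first. Rb1, the pocket protein that restrains E2F transcription factors, had 11 TPM in the normal library and 2.65 to 3.44 TPM in the transformed ones, although genes along its whole chromosome were lower there. Trp53 had 115 TPM in normal and 2.85 to 5.26 TPM in the transformed libraries. Myc had 39.6 TPM in normal, 57.3 in RPM, 95.1 in RPMN, 62.2 in RPMP and 65.3 in RPMNP. Nf1, which encodes the RAS-inactivating protein neurofibromin, had 9.22 TPM in RPM and 12.6 in RPMP against 10.4 in RPMN and 10.3 in RPMNP, the libraries labelled as its knockout. Pten, the lipid phosphatase that opposes PI3 kinase, had 39.1 TPM in RPM and 47.4 in RPMN against 38.2 in RPMP and 37.8 in RPMNP. The labels do not say which part of Nf1 or Pten was edited, and a gene-level TPM can hold reads of an edited transcript that is still made. These levels therefore do not check either label, and the directions given below for the Nf1 and Pten knockouts rest on the labels alone.

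**Figure D1:**
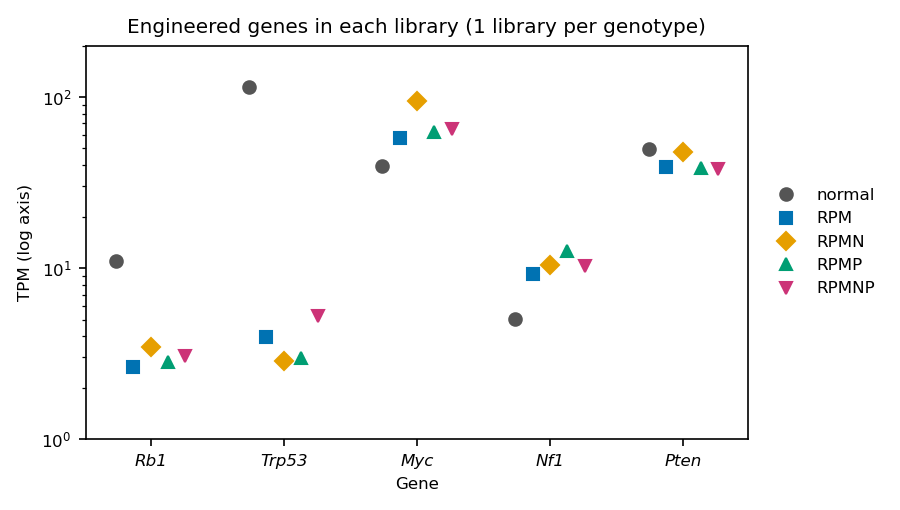
Each symbol gives the TPM (log axis) of 1 engineered gene in 1 library, with 1 library per genotype and no error bars. Rb1 and Trp53 lie lower in all 4 transformed libraries than in normal, while Nf1 (9.22 to 12.6 TPM) and Pten (37.8 to 47.4 TPM) lie at similar levels in the transformed libraries labelled with and without their knockout.

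The series asks what loss of Rb1 and Trp53 with Myc overexpression does to this epithelium. The genes with the lowest ratios of RPM to normal included several secreted products that were abundant in normal. Prap1, a secreted acidic protein, had 12902 TPM in normal and 0.978 TPM in RPM. Complement C3 had 9235 TPM against 4.80 TPM, lactoferrin (Ltf) 11938 TPM against 11.1 TPM, and the peptide hormone precursor Guca2b 9794 TPM against 0.930 TPM. The steroid-metabolising enzyme Akr1c18 (4571 TPM), the water channel Aqp8 (3563 TPM) and the protease inhibitor Serpina1e (3240 TPM) were at 1.90, 6.51 and 0.250 TPM in RPM. S100g and Prl6a1, at 885 and 744 TPM in normal, were listed at 0 in RPM. Pinlyp, Chil4 and the matrix protein Fbln1 completed the genes with the lowest ratios. At the other end, the cell-surface antigen Gpa33 had 0.460 TPM in normal and 341 TPM in RPM, S100a14 had 7.13 and 1324 TPM, and the chloride channel Clcnka 0.0623 and 144 TPM. The serine proteases Prss22 (573 TPM in RPM) and Prss27 (96.3 TPM), the protein C receptor Procr (191 TPM), the cornified-envelope gene Sprr2a2 (456 TPM) and the LDL receptor regulator Pcsk9 (188 TPM) were each under 10 TPM in normal. So were Acap1, Apobr, Azgp1 and Ifi27l2a, an interferon-induced gene at 5.54 TPM in normal and 370 TPM in RPM. Each of these genes was at least 2-fold apart in the same direction in all 4 transformed libraries.

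Counted over all genes, 2265 were at least 2-fold higher and 1848 lower in RPM than in normal. The totals for the 4 transformed libraries were 4113 to 4592 genes against normal, compared with 258 to 1730 genes between any 2 transformed libraries. Rank correlations across genes ran from 0.804 to 0.815 between normal and a transformed library and from 0.949 to 0.987 among transformed libraries. A set of 1197 genes was higher and 1403 lower in all 4. Because the same normal library enters all 4 ratios, 100 simulated data sets with an unchanged normal library were counted in the same way and gave means of 59.9 and 58.7 genes, while independent lists of these sizes would share 16.5 and 6.36. The simulation gave the normal library the spread of the 4 transformed libraries, which correlate more closely with each other than with normal. It therefore cannot show how many genes another normal culture would set apart. Part of the excess may come from the shared library. The balance of directions depends on the scaling. The median log2 ratio of all genes to normal was 0.28 in RPM, 0.36 in RPMN, 0.34 in RPMP and 0.24 in RPMNP, and rescaling by the median ratio moved that of RPM to −0.03. It changed the RPM counts to 1511 higher and 2377 lower (38.9% higher instead of 55.1%) and those in all 4 to 746 and 1776 (29.6% higher instead of 46.0%).

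Gene lists written in advance were compared with 10000 random lists matched on mean expression, and a list is said to stand apart when its median log2 ratio lay outside the central 95% of them. Members of a list tend to vary together, so random lists are a narrow reference. Of 37 lists, 9 stood apart as higher and 7 as lower in all 4 transformed libraries.

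Cell cycle genes were higher in every transformed library. All 38 E2F and S-phase genes had a positive ratio in all 4 libraries, 34 were at least 2-fold higher in RPM, and the list median was 1.48 in RPM, 1.70 in RPMN, 1.61 in RPMP and 1.55 in RPMNP. The S-phase cyclin gene Ccne2 had 5.53 TPM in normal and 31.7 TPM in RPM, and the transcription factor gene Mybl2 had 3.51 and 21.2 TPM. Of 31 mitosis genes, 29 were at least 2-fold higher in RPM (median 1.72), with the kinase Aurka at 23.1 and 116 TPM and Bub1 at 9.62 and 44.1 TPM. The medians were 2.25 in RPMN, 1.78 in RPMP and 2.26 in RPMNP. Of 23 homologous recombination genes, which repair DNA breaks from a sister copy, 16 were at least 2-fold higher in RPM (median 1.21), Rad51 with 10.7 and 42.7 TPM among them, while Brca1 had 5.92 and 5.88 TPM. Among 12 cyclin D and CDK inhibitor genes, 7 were at least 2-fold higher and 1 lower in RPM (median 1.44), but with a pseudocount of 5 TPM the list did not stand apart in RPMP. Cdkn2a, which encodes p16 and p19Arf, had 27.4 TPM in normal and 618 in RPM, whereas the p53 target Cdkn1a had 236 and 39.4 TPM. The p53 target list as a whole was lower, with a median of −0.57 in RPM, −0.38 in RPMN, −0.45 in RPMP and −0.85 in RPMNP. Of its 28 members, 10 were at least 2-fold lower and 0 higher in RPM. Gdf15 had 145 TPM in normal and 0.146 TPM in RPM, Phlda3 had 123 and 6.90 TPM, and the receptor gene Eda2r had 16.4 and 0.141 TPM, while Pmaip1 (35.8 and 58.4 TPM) and Polk (9.50 and 16.7 TPM) lay on the other side. Ribosome biogenesis and MYC target genes had a median of 0.52 in RPM, which 70.3% of random lists lay below, with 2 of 35 members at least 2-fold higher (Nop58 and Tcof1). The list stood apart as higher in RPMN (0.92), RPMP (0.86) and RPMNP (1.13).

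Both differentiated cell types of the tube had lower marker levels. Of 20 oviduct secretory cell genes, 16 were at least 2-fold lower and none higher in RPM (median −4.27), and the medians were −4.21 in RPMN, −3.84 in RPMP and −3.64 in RPMNP. Besides C3 and Ltf, the iron-sequestering Lcn2 had 13661 TPM in normal and 108 in RPM, and the immunoglobulin receptor Pigr had 453 and 2.63 TPM. Wfdc2, the gene for the tumour marker HE4, did not follow, with 2235 and 2641 TPM. Of 36 multiciliated cell genes, 30 were at least 2-fold lower in RPM (median −2.62), including the cilium genes Pifo (33.1 and 0.179 TPM), Tppp3 (33.0 and 0.584 TPM) and Dynlrb2 (26.8 and 0.485 TPM), and Ccdc153, which was listed at 0. Mlf1 and Enkur lay on the other side, and Foxj1, the transcription factor that drives ciliogenesis, had 102 TPM in normal and 119 TPM in RPM but 11 to 31.1 TPM in the other transformed libraries. With only genes of at least 5 TPM kept, the multiciliated median was −2.82 in RPM, but the list lay at the 16.2 percentile of random lists and no longer stood apart. Ovarian carcinoma markers differed in both directions. Sox17 had 45.7 TPM in normal and was listed at 0 in the transformed libraries, Pax8 had 220 and 13.4 TPM and Folr1 26.7 and 0.0302 TPM, while the tight junction genes Cldn4 (305 and 2727 TPM) and Cldn3 (239 and 871 TPM) were higher in RPM. The median of these 14 markers was −0.18 in RPM and −0.98 in RPMNP, and the list did not stand apart in RPM, RPMN and RPMP without the filter on low values or with only genes of at least 5 TPM, nor in RPMN and RPMP with a pseudocount of 0.1 TPM. Wnt target and stem cell genes had a median of −0.81 in RPM, with 8 of 18 at least 2-fold lower and 4 higher, Cd44 (14 and 99.6 TPM) being higher and Tnfrsf19 (27.1 and 0.458 TPM), on the chromosome of Rb1, lower. This list did not stand apart in RPMP with a pseudocount of 5 TPM, without the filter, with only genes of at least 5 TPM, or without the chromosome that carries Rb1, nor in RPMN with that pseudocount (3.36 percentile).

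Interferon-stimulated genes had the highest list median in RPM and RPMP, at 2.5 and 3.27, and medians of 1.84 in RPMN and 1.31 in RPMNP. Of 26 members, 23 were at least 2-fold higher in RPM. The ubiquitin-like modifier Isg15 had 85.6 TPM in normal and 1927 TPM in RPM, the chemokine Cxcl10 had 3.21 and 92.9 TPM, and the transcription factor Irf7 had 22.2 and 510 TPM, while the adaptor Sting1 had 216 and 79.4 TPM. Antigen presentation genes were higher in RPM (median 1.94, 11 of 14 at least 2-fold higher), RPMN (1.18) and RPMP (2.55), but in RPMNP the median of 0.79 did not stand apart, except without the filter, with a pseudocount of 0.1 TPM or after rescaling without the top 100 genes. The immunoproteasome subunits Psmb9 (6.27 and 61.9 TPM) and Psmb8 (29.1 and 207 TPM) had the highest ratios along with H2-Q4 and Tap1. Epithelial cytokines and chemokines were lower as a list, with medians of −0.47 in RPM, −0.81 in RPMN, −0.07 in RPMP and −0.71 in RPMNP. In RPM 10 of 23 were at least 2-fold lower and 6 higher. The chemokine genes Cxcl5 (2044 and 8.77 TPM) and Ccl28 (333 and 2.45 TPM) were lower, and Cxcl15 (5.64 and 67.4 TPM) and Ccl5 (3.89 and 37.6 TPM) higher. In RPMP the cytokine list did not stand apart without the filter, after 2 of the 3 rescalings, or without the chromosomes that carry Cdk6 and Dhfr, and in the last setting not in RPM either.

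Among metabolic lists, those of sterol synthesis, glycolysis and ATF4 genes were higher, while that of fatty acid synthesis genes did not stand apart. Sterol synthesis genes had medians of 1.02 to 1.26, with 13 of 22 at least 2-fold higher in RPM and Insig1 at 107 and 359 TPM, although Dhcr24 had 948 and 685 TPM. Glycolysis genes had medians of 0.88 to 1.39, with the phosphofructokinase Pfkp at 11.4 and 60.5 TPM and the glucose transporter Slc2a1 at 74.6 and 247 TPM, while the lactate exporter Slc16a3 had 7.80 and 0.837 TPM. ATF4 and amino acid genes had medians of 0.89 to 1.84, with the serine synthesis genes Psph (9.23 and 63.2 TPM) and Phgdh (125 and 485 TPM) among the highest. Glycolysis genes did not stand apart in RPMP with a pseudocount of 5 TPM, nor sterol synthesis genes in RPMNP without the chromosomes of Cdk6 and Dhfr. Replication-dependent histone genes had medians of 0.30 in RPM, 0.75 in RPMN, 1.35 in RPMP and 1.35 in RPMNP. The RPM value did not stand apart with a pseudocount of 5 TPM, with only genes of at least 5 TPM, or when chromosomes were left out or centred. Without the chromosomes of Cdk6 and Dhfr the RPMN and RPMP values did not either. Leaving out a chromosome also takes out the list members on it. The mitochondrially encoded genes had medians of −0.76 in RPM, −1.08 in RPMN, −0.97 in RPMP and −0.86 in RPMNP, and took 11.7% of the TPM in normal against 6.42% to 7.75%. Cytosolic ribosomal protein genes had a median of 0.08 in RPM, below that of all random lists, and this sign turned after rescaling by the median ratio (−0.25), after rescaling without the top 100 genes (−0.13) and with ratios centred per chromosome (−0.19).

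**Figure D2:**
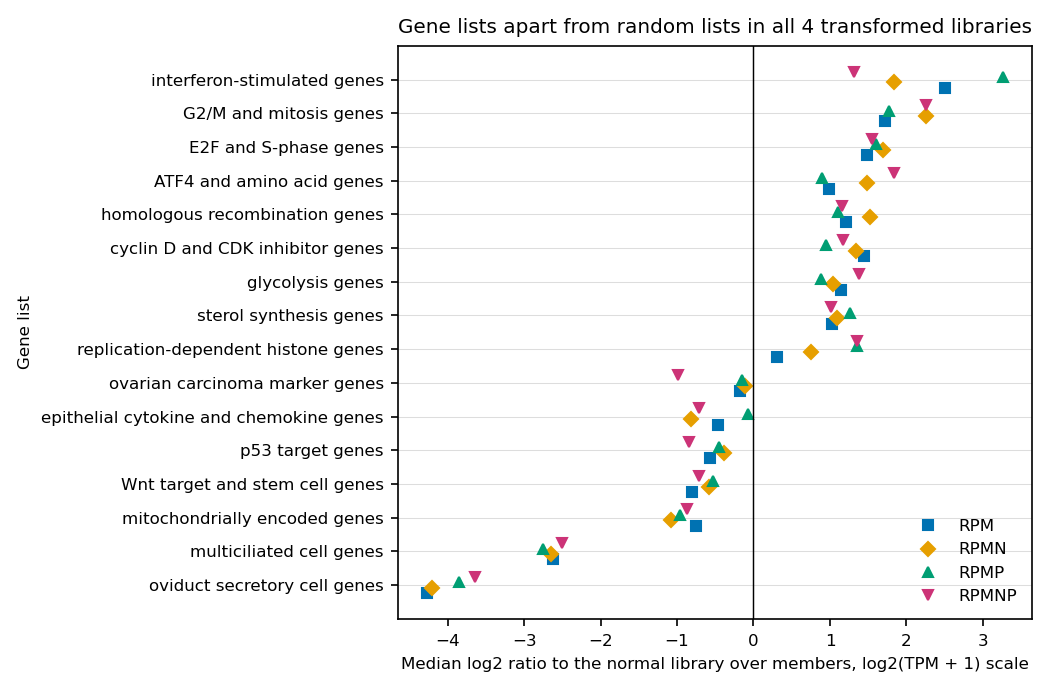
Each symbol gives the median over list members of the log2 ratio, on the log2(TPM + 1) scale, between 1 transformed library and the normal library, for the 16 lists that stood apart on the same side in all 4. Oviduct secretory genes lie between −4.27 and −3.64 and interferon-stimulated genes between 1.31 and 3.27.

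The remaining lists did not stand apart in all 4 libraries. NRF2 target genes had a median of −0.67 in RPM, below all random lists, and −0.00 in RPMNP (7.88 percentile). Notch pathway genes had 0.99 in RPM (99.6 percentile), with Jag2 and Nrarp higher and Jag1 lower, and sex hormone receptor and response genes had −1.16 (1.76 percentile), with the progesterone receptor Pgr at 33.3 and 0.382 TPM. Hypoxia genes had 0.79 in RPM and −0.65 in RPMP. MAPK output genes had 0.62 in RPM (93.8 percentile), with the AP-1 subunit Fosl1 and Etv4 among the highest. Mesenchymal transition genes had 0.72 in RPM (98.7 percentile), with Serpine1 at 581 TPM in RPM but vimentin (Vim) at 10.7 TPM in normal and listed at 0 in RPM. The medians in RPM were 0.14 for FOXO targets, 0.74 for epithelial junction and keratin genes, 0.02 for fatty acid synthesis genes, 0.71 for 5 fetal and germline genes, 0.74 for immediate early and stress genes, −0.22 for HOX and Mullerian patterning genes, −0.75 for squamous keratin genes and −0.14 for neuroendocrine and tuft genes, none of them apart. The 4 measured intestinal and gastric markers had 1.04 in RPM (98.9 percentile). Most markers of fibroblasts, endothelium, leukocytes and smooth muscle stayed under 1 TPM in all 5 libraries. Of 15 fibroblast markers 2 reached 1 TPM in any library, and apart from Fbln1 (551 TPM in normal, 0.181 in RPM) none exceeded 1.31 TPM. Of 10 endothelial markers 2 did, led by Cdh5 with 14.1 TPM in normal. Of 16 leukocyte markers 4 did, and their median ratio of −1.18 in RPM did not stand apart. They were Lyz2 (15.3 TPM in normal, listed at 0 in RPM), Ptprc (4.30 and 0.0263 TPM), C1qa and Csf1r (3.70 and 38.7 TPM). The 3 measured smooth muscle markers had a median of −0.61 in RPM (25.6 percentile). The 4 listed Y-chromosome genes were at 0 in all 5 libraries.

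Whole chromosomes differed in expression level between libraries, which bears on Rb1 and its neighbours. Medians of log2 ratios to normal were taken per chromosome over genes with a mean of at least 5 TPM, relative to the median of all genes. The 321 genes on the chromosome that carries Rb1 had medians of −0.88 in RPM, −0.86 in RPMN, −0.87 in RPMP and −0.80 in RPMNP. All 10 blocks of neighbouring genes along it lay between −1.07 and −0.56 in the 4 libraries. The 664 genes on the chromosome that carries Cdk6 had medians of 0.48 in RPM, 0.38 in RPMN and 0.50 in RPMNP, and 0.05 in RPMP. On the chromosome that carries Dhfr the median was −0.44 in RPMP and between 0 and 0.02 in the other 3. There, 5 consecutive blocks of 175 genes, from Sptlc1 to Ppwd1, had medians of −1.1 to −0.62 in RPMP. Other chromosomes had medians between −0.33 and 0.21, and both ends of this range came from RPMNP. There the chromosomes of Kras, Mx1 and Cdk4 had −0.33, −0.32 and −0.27, where random sets of as many genes went no lower than −0.13, −0.18 and −0.14. The chromosome at 0.21 had blocks of 0.09 to 0.35 in RPMNP, and random sets there reached 0.10. Of 427 genes on the chromosome of Rb1, 22.0% were at least 2-fold lower in all 4 transformed libraries, against 10.5% of other genes.

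**Figure D3:**
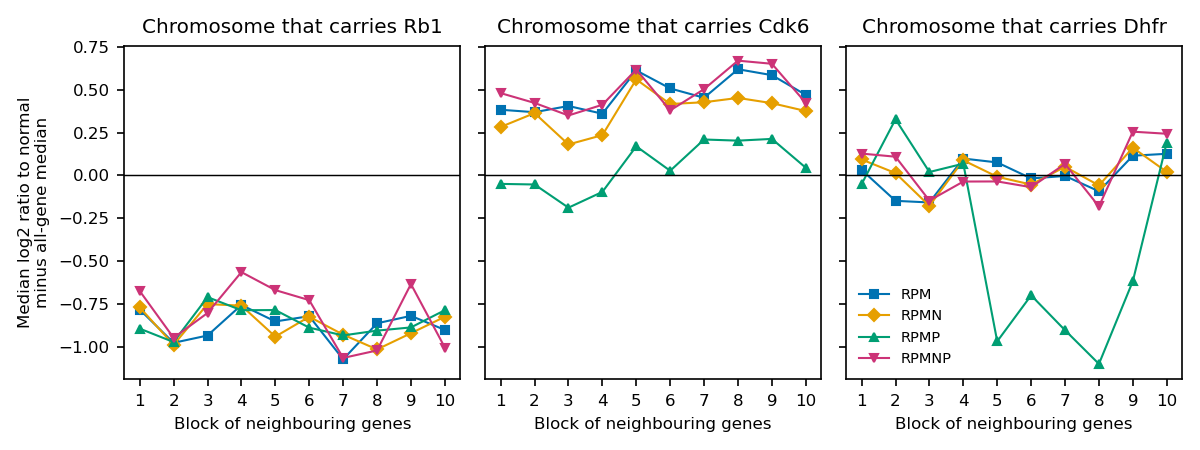
Lines join the medians of the log2 ratio to normal (minus the median of all genes) in 10 blocks of neighbouring genes along each of 3 chromosomes, with 1 line per transformed library. The chromosome that carries Rb1 lies at −0.56 or lower along its length in all 4 libraries, that of Cdk6 lies lower in RPMP than in the others, and blocks 5 to 9 of the chromosome of Dhfr lie at −1.1 to −0.62 in RPMP alone.

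The Nf1 knockout was compared in both backgrounds, as RPMN against RPM and as RPMNP against RPMP, contrasts that share no library. Interferon-stimulated and antigen presentation genes were lower with the Nf1 label in both. The interferon-stimulated median was −0.66 in RPMN against RPM and −1.79 in RPMNP against RPMP, with 21 of 26 members lower in both and 6 at least 2-fold lower in both. Ifit3 had 321 TPM in RPM and 109 in RPMN, and 1270 in RPMP and 51.5 in RPMNP, while the nucleic acid sensor gene Zbp1 had 42.9 and 12.8, and 158 and 16.5 TPM. The antigen presentation medians were −0.68 and −1.76, with 12 of 14 members lower in both. B2m, the common light chain of MHC class I, had 4939 and 2446 TPM in the first contrast and 6316 and 1819 TPM in the second, and H2-T23 had 264 and 127, and 400 and 73.9 TPM. The peptidase Erap1, within the stretch of genes that was lower in RPMP, went the other way (51.0 and 60.7, and 30.6 and 45.6 TPM). Cytokines and chemokines had medians of −0.31 and −0.84, with 3 of 23 members at least 2-fold lower in the first and 8 in the second contrast. Only 11 of the 23 were lower in both, and 3 were higher in both. The 2 at least 2-fold lower in both were Tnf (26.4 and 6.0, and 151 and 7.39 TPM) and Ccl5 (37.6 and 8.65, and 93.6 and 11.4 TPM). On the mean of both contrasts, Cxcl5 (1.25), Cxcl2 (0.75) and Il33 (0.58) went the other way.

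On the higher side with the Nf1 label stood 3 lists in both backgrounds. G2/M and mitosis genes had medians of 0.52 and 0.55, and 24 of 31 were higher in both, although none was 2-fold higher in both. Birc5 had 50.6 and 62.6, and 25.8 and 73.4 TPM, and Mki67 went the other way in the first contrast (36.7 and 22.7 TPM). Ccnb1, with the largest mean ratio of this list, lies within that stretch as well. Ribosome biogenesis and MYC target genes had medians of 0.44 and 0.27, with 27 of 35 higher in both, led by Cad, the first enzyme of pyrimidine synthesis (32.7 and 67.6, and 40.0 and 62.0 TPM). ATF4 and amino acid genes had medians of 0.46 and 0.85, with 14 of 18 higher in both. The transcription factor Atf5 had 59.8 and 124, and 72.4 and 203 TPM, and the proline synthesis gene Pycr1 had 4.86 and 9.42, and 2.12 and 10.3 TPM, while Nupr1 went the other way (1498 and 766, and 3576 and 748 TPM). These 6 lists stood apart under each alternative setting tried. Many lists stood apart in each single contrast, however. Of 37, 9 were higher and 6 lower in RPMN against RPM, and 8 and 7 in RPMNP against RPMP. Some lists could therefore share a side in both contrasts without a common cause. MAPK output genes, which report signalling downstream of RAS, did not differ in 1 direction. Their median was 0.20 in RPMN against RPM (98.5 percentile) and −0.46 in RPMNP against RPMP (0.33 percentile). E2F and S-phase genes had 0.23 (99.8 percentile) and 0.05 (94.7 percentile).

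Single genes at least 2-fold apart in both Nf1 contrasts numbered 24 higher and 65 lower, where independent lists would share 4.19 and 14.5, and 29 genes were 2-fold apart in opposite directions. With 1 library per genotype this excess cannot be told apart from other differences between the lines. The remaining pairing of the same libraries is RPMNP against RPM with RPMP against RPMN. It had 54 higher and 86 lower in both, where 15.2 and 24.5 would be shared, and 164 in opposite directions. This pairing is no reference free of the knockouts. By construction, genes on the same side in it have a mean Pten ratio of at least 2-fold. Those on opposite sides have a mean Nf1 ratio of at least 2-fold. Cyba, a subunit of the NADPH oxidase, had 13.3 TPM in RPM and was listed at 0 in RPMN, and had 29.9 and 0.176 TPM in the second contrast. Gde1, a glycerophosphodiester phosphodiesterase, had 34.9 and 2.06, and 33.4 and 0.155 TPM. The matrix protease Mmp7 (60.4 and 4.90, and 25.5 and 0.797 TPM), the membrane protease Hpn (24.5 and 2.41, and 36.5 and 2.14 TPM), Mxra8, Muc20, Lcn2 and the keratin Krt20 were also lower. Fgf13 was the highest (11.5 and 48.7, and 5.88 and 39.1 TPM), followed by Ccdc3, the peptide gene Adm2 and Cth, an enzyme of cysteine synthesis (12.9 and 37.1, and 8.21 and 37.3 TPM). The amino acid transporter Slc38a1, the peptide gene Apln, Pate14, Klra4 and Maoa were higher as well. Across all genes the ratios of both contrasts had a Pearson correlation of 0.148 (SD 0.019 from resampling chromosomes) and a Spearman correlation of 0.055. Genes are not independent replicates. With a pseudocount of 0.1 TPM the counts were 99 and 134, and with 5 TPM they were 4 and 26.

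**Figure D4:**
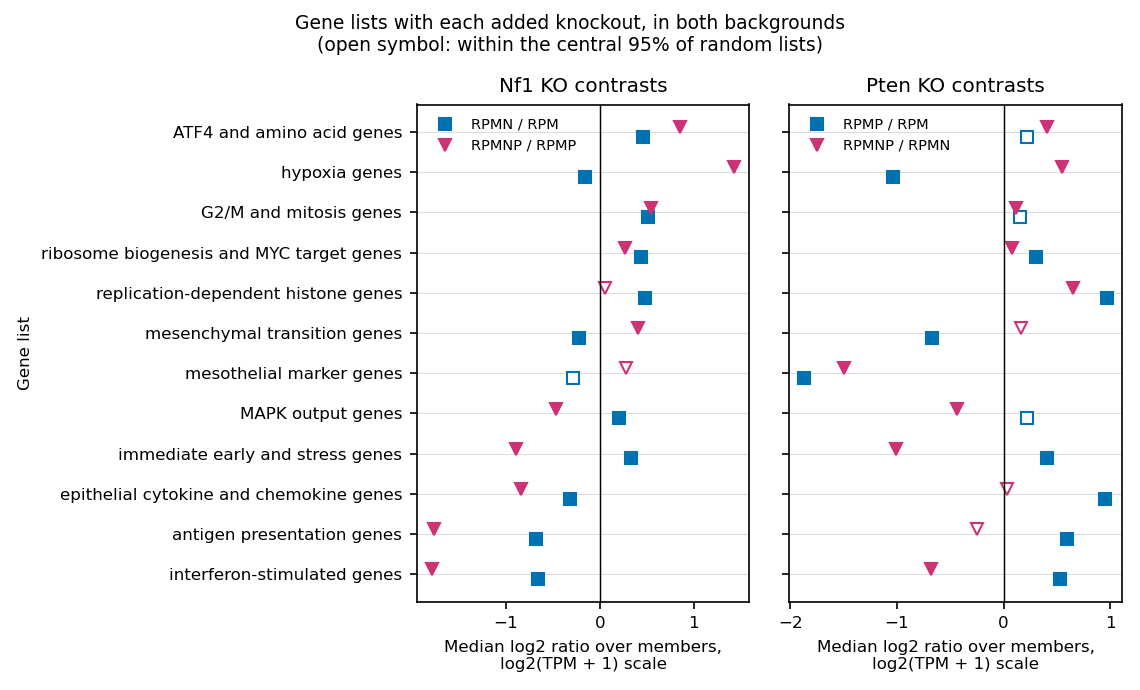
Symbols give the median log2 ratio over list members, on the log2(TPM + 1) scale, for the Nf1 contrasts (left) and the Pten contrasts (right), squares for the knockout added to RPM and triangles for the knockout added to the other knockout. Filled symbols mark lists outside the central 95% of random lists. Interferon-stimulated genes lie at −0.66 and −1.79 in the Nf1 contrasts, and at 0.53 and −0.68 in the Pten contrasts.

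The Pten knockout was compared as RPMP against RPM and as RPMNP against RPMN. Of 37 lists, 8 stood apart as higher and 5 as lower in the first contrast, and 9 and 6 in the second. In both contrasts 2 were higher and 1 lower, about what unrelated calls at these rates would give. Sharing a side is therefore no evidence of a common cause for these lists. Of the 4 measured mesothelial markers, 3 were at least 2-fold lower with the Pten label in both backgrounds, with list medians of −1.87 and −1.50. Wt1, a transcription factor also used as a marker of serous ovarian carcinoma, had 17.2 TPM in RPM and was listed at 0 in RPMP, and had 17.5 and 1.0 TPM in the second contrast. Msln had 283 and 120, and 224 and 62.8 TPM, and Upk3b 14.8 and 1.79, and 3.80 and 1.13 TPM. Replication-dependent histone genes were higher, with medians of 0.97 and 0.65 and 28 of 45 higher in both, among them H4c8 (8.03 and 14.4, and 6.92 and 42.6 TPM). Ribosome biogenesis and MYC target genes had medians of 0.31 and 0.08 with 16 of 35 higher in both, including Ncl (217 and 312, and 309 and 416 TPM). The histone list lay at the 77.9 percentile in the first contrast without the chromosomes of Cdk6 and Dhfr, so it then did not stand apart. Nor did the ribosome biogenesis list in the second without the chromosome of Rb1 (97.3 percentile). Leaving out a chromosome also takes out the list members on it, so it does not separate a chromosome shift from a shorter list. With ratios centred per chromosome both lists still stood apart in both contrasts. FOXO target genes, which the PI3 kinase pathway represses, had medians of 0.07 (41.6 percentile) and −0.41 (1.74 percentile), with Pik3ip1 (16.1 and 5.56, and 10.4 and 6.67 TPM) and Cited2 lower in both.

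In both Pten contrasts, 48 genes were at least 2-fold higher and 81 lower, against 11.2 and 20.8 for independent lists, and 77 were 2-fold apart in opposite directions. The remaining pairing shared 54 and 86, but by construction these genes have a mean Pten ratio of at least 2-fold, so they are no separate reference. Among the transformed libraries, the mean Pten ratio held 31.3% of the sum of squares over all genes, after subtracting medians. The mean Nf1 ratio held 38.5%, and the interaction, which is the difference between both backgrounds, 30.2%. Lines that differed at random would on average give equal shares to the Pten, Nf1 and interaction contrasts. These shares therefore do not measure an effect of either knockout. Cpn1, a subunit of carboxypeptidase N, had 7.01 and 55.0, and 3.21 and 48.9 TPM. The chemokines Ccl28 (2.45 and 19.4, and 2.29 and 18.9 TPM) and Cxcl2 and the metallothionein Mt2 (2.87 and 14, and 3.10 and 122 TPM) were higher. So were the MHC class II pathway genes Cd74 (9.28 and 33.9, and 6.11 and 37.7 TPM) and H2-DMb1. The class II genes H2-Aa, H2-Ab1 and H2-Eb1, and Ciita, were at most 0.273 TPM in any library. Psors1c2, Smim10l2a, Tmem213 and Sult1d1 were higher as well. Besides Wt1, the lower genes included the YAP target Ccn2 (951 and 289, and 585 and 105 TPM), the AP-1 subunit Jun (287 and 60.9, and 361 and 111 TPM), the carboxylesterase Ces2g, Tnfrsf26 and AU018091. Cwh43, Lrrc8c and Odaph, on the chromosome of Cdk6, and Ctla2b, on that of Dhfr, were lower too. The Pten contrasts had a Pearson correlation across genes of 0.016 (SD 0.014 from resampling chromosomes) and a Spearman correlation of −0.082. With a pseudocount of 0.1 TPM the counts were 150 and 163, and with 5 TPM they were 12 and 32.

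The library with both added knockouts was set against each of the other 3 transformed libraries. RPMNP had 178 genes at least 2-fold higher and 244 lower than in all 3, compared with 197 and 155 for RPMP, 44 and 12 for RPM, and 10 and 23 for RPMN. The balance of directions in RPMNP depends on the scaling. It was 207 higher and 188 lower after rescaling by the median ratio, and 244 and 209 without mitochondrial and ribosomal protein genes. Without the top 100 genes it was 242 and 236, and with ratios centred per chromosome 203 and 169. The lower genes were led by the interferon-inducible Ifi209 (7.81 TPM against 77.8 to 82.1), Ifi27l2a (33.2 TPM against 209 to 465) and the DNA sensor Aim2 (0.948 TPM against 11.6 in RPMP), with Mgat3 and Itih2. The higher genes were led by Pate14, the fatty acid receptor Ffar4 (14.5 TPM against 0.192 to 0.566), Mt2, the homeobox gene Hoxd8 (24.2 TPM against 1.33 to 2.66) and Tead2, a partner of YAP (38.7 TPM against 2.87 to 6.08). Interferon-stimulated genes had medians of −1.30 against RPM, −0.68 against RPMN and −1.79 against RPMP. Immediate early and stress genes had −0.66, −1.0 and −0.89, and FOXO targets −0.58, −0.41 and −0.50. ATF4 and amino acid genes were higher against each (0.98, 0.41 and 0.85), as were hypoxia genes (0.30, 0.55 and 1.43), G2/M genes (0.62, 0.11 and 0.55) and cytosolic ribosomal protein genes (0.45, 0.34 and 0.49), which took 16.1% of the TPM in RPMNP and 11.2% to 12.5% in the others. The 5 fetal and germline genes also had positive medians (0.78, 1.0 and 1.02), but with only genes of at least 5 TPM kept the value against RPMP turned to −0.31 and that against RPMN no longer stood apart (79.7 percentile). All of these medians stood apart at the main setting, but against RPMP the FOXO list did not with ratios centred per chromosome (17.6 percentile) or a pseudocount of 5 TPM (3.12 percentile), nor the fetal list with that pseudocount or without the chromosomes of Cdk6 and Dhfr.

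RPMP differed in a different way. Its highest genes were Fxyd2 (65.4 TPM against 0.206 to 0.757), the phosphate transporter Slc17a1, the cadherin Cdh16 (24.0 TPM against 0.302 to 0.846), Ltf (146 TPM against 0.795 to 11.1) and Msmp. Its lowest were the CDK inhibitor Cdkn1c (0.365 TPM against 71.8 to 118), the mitochondrial adenylate kinase Ak4, the integrin Itgb2, Pdk1 and the lysosomal lipase Lipa. In RPM the plasminogen activator inhibitor Serpine1 (581 TPM against 49.7 to 153), Foxj1 (119 TPM against 11 to 31.1), Rangrf, Upk3b and Ctla2a were higher than in the other 3, and Gpx2 (56.1 TPM against 181 to 380), Smim10l2a, Pcdhgc3 and H4c9 lower. In RPMN, Tnfrsf26, Nipal4, Mest and Klra4 were higher and Mia, Selenom, Sult1d1, Tspan12 and Fam171a1 lower. The RPMNP and RPMP counts depended on the pseudocount, with 365 and 394 genes for RPMNP and 303 and 375 for RPMP at 0.1 TPM, and 46 and 119, and 81 and 59, at 5 TPM. With only genes of at least 5 TPM kept, RPMNP had 105 higher genes, and without the chromosomes of Cdk6 and Dhfr, RPMP had 102 lower genes.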

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

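The gene lists, the filter and the pseudocounts in this part were planned, and the tests of explanations for the hypoxia genes were chosen after the results were seen. In 5 gene lists the ratio with an added knockout stood apart in opposite directions in both backgrounds, and with 1 library per genotype none of these differences was tested. Many lists stood apart in each single contrast, so unrelated calls would also give several lists on opposite sides. The values below are medians over members of the interaction, which is the log2 ratio of RPMNP to RPMP minus that of RPMN to RPM (the same number results for Pten). For interferon-stimulated genes it was −1.23, with a Pten ratio of 0.53 in RPMP against RPM and −0.68 in RPMNP against RPMN. For immediate early and stress genes it was −1.22, the Nf1 ratios being 0.33 and −0.89 and the Pten ratios 0.40 and −1.0. For MAPK output genes it was −0.71, with Nf1 ratios of 0.20 and −0.46. For mesenchymal transition genes it was 0.53, with Nf1 ratios of −0.23 and 0.41, of which the first did not stand apart without the filter on low values (2.70 percentile) and the second did not with a pseudocount of 5 TPM (96.5 percentile).

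The largest was 1.69, for hypoxia genes. They were lower in RPMP than in RPM (median −1.04, 7 of 14 at least 2-fold lower), RPMN and RPMNP, with the carbonic anhydrase Car9 at 10.8 TPM against 70.0, 86.6 and 47.7 and the kinase Pdk1 at 6.29 TPM against 50.6, 46.8 and 84.2. Expression shifts of whole chromosomes do not account for this, since the RPMP to RPM median was −1.17 with ratios centred per chromosome. Shifts of part of a chromosome, which centring on the chromosome median leaves in, were not tested. The same list was higher in RPMNP than in RPMN (median 0.55), but this value is part of what drew attention to the list and is no separate test of an effect of Pten loss. Oxygen supply or density of the RPMP culture at harvest may differ from the others, and with 1 library per genotype this cannot be told apart from loss of Pten or another effect of the genotype.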

How the results depend on the processing

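The alternatives that left out or centred chromosomes were chosen after seeing the data. At 0.1 TPM, 99 and 134 genes were higher and lower in both Nf1 contrasts, 150 and 163 in both Pten contrasts, 365 and 394 in RPMNP and 303 and 375 in RPMP against the other 3, and the correlation of the Pten contrasts was 0.037. At 5 TPM the counts were 1457 and 1047 for RPM against normal, 692 and 807 in all 4 transformed libraries, 4 and 26 for Nf1, 12 and 32 for Pten, 46 and 119 for RPMNP and 81 and 59 for RPMP, with a Pten correlation of −0.024. A larger pseudocount shrinks the ratios of genes with low values by construction. With a filter of 5 TPM, RPMNP had 105 higher genes, and the median of the fetal and germline genes in RPMNP against RPMP turned to −0.31. The ribosomal protein median in RPM turned to −0.25 after rescaling by the median ratio, to −0.13 without the top 100 genes and to −0.19 with ratios centred per chromosome. Rescaling by the median ratio gave 746 genes higher in all 4, leaving out the top 100 genes gave 41 higher for Nf1, and centring per chromosome gave 1447 genes higher in RPM and 753 in all 4, because it removes the positive median of all genes. Without the chromosomes of Cdk6 and Dhfr, 102 genes were lower in RPMP, since 39 of the 155 lie on the chromosome of Dhfr and 14 on that of Cdk6. The causes of the other changes were not tested.

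The 6 lists apart in both Nf1 contrasts remained so in all 10 settings. Of the 16 lists apart in all 4 transformed libraries, 12 to 16 remained, and of the 3 for Pten, 2 or 3. Lists were gained as well in 9 of the settings. Apart in all 4 libraries became intestinal and gastric markers in 4 settings, antigen presentation genes in 3, and sex hormone, Notch and fetal genes in 2 each. HOX genes were gained for Pten in 3, and for Nf1 histone genes in 2 and sex hormone and E2F genes in 1 each. Without mitochondrial and ribosomal protein genes those lists have no value. No paired analysis was possible because each genotype has 1 library. Depth is unknown, so differences among genes near 1 TPM cannot be separated from counting error.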

Other observations

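The gene lists and the 3 rescalings used in this part were planned, and the tests of explanations were chosen after the results were seen. Genes of interferon itself were at the floor in most libraries. Ifnb1 had 0.989 TPM in RPM and 1.57 TPM in RPMP, 0.106 TPM in RPMN, and was listed at 0 in normal and RPMNP. Ifnl2 had 0.772 TPM in RPMP and 0.0933 TPM in RPMNP and was listed at 0 in the others. Ifne, the interferon made constantly by epithelium of the female reproductive tract, had 27.3 TPM in normal and was listed at 0 in all 4 transformed libraries. These genes were chosen after the lists were seen.

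The estrogen receptor gene Esr1 had 97.4 TPM in normal, 48.2 in RPM, 59.6 in RPMN, 59.2 in RPMP and 28.3 in RPMNP, while Pgr had 33.3 TPM in normal and 0.161 to 3.50 TPM in the transformed libraries. Of 17 listed fetal and germline genes 5 were measured, and the list did not stand apart in RPM or RPMP. Igf2bp1 had 1.08 TPM in normal and 39.6 to 51.1 TPM in the transformed libraries, and Afp 0.796 TPM and 4.44 to 48.6 TPM, whereas most other members, such as Igf2 and Lin28b, stayed under 1 TPM in all 5. The intestinal transcription factor Cdx2 was listed at 0 in normal and had 3.25 TPM in RPM, 5.30 in RPMN, 8.63 in RPMP and 12.1 in RPMNP.

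Genes along the whole chromosome that carries Rb1 were lower in all 4 transformed libraries. GC content or transcript length bias does not account for it, since with ratios centred in 50 bins of both properties the median nearest 0 was still −0.82 (98.4% of the genes had a value). A change local to Rb1 and its neighbours does not either, because the 225 genes outside the block of Rb1 and the blocks beside it had medians of −0.86 to −0.79 in the 4 libraries (bootstrap SD at most 0.0763), where random sets of as many genes had medians no lower than −0.19. This test was added after single blocks had been compared with 1000 random sets of 32 genes, below which all 10 blocks lay in RPM, RPMN and RPMP but 6 of 10 in RPMNP. The 4 chromosome medians, −0.88 to −0.80, are near the log2 ratio of −1 that loss of 1 of 2 copies would give, and are consistent with such a loss in cells from which all 4 lines descend, a hypothesis that DNA data would have to test. If it holds, the lower level of other genes on this chromosome would be shared by all 4 libraries without being an effect of any single engineered gene.

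Interferon-stimulated and antigen presentation genes were lower in both libraries labelled with the Nf1 knockout. The median of 16 leukocyte markers was 0 TPM in all 4 transformed libraries, but cells of a single lineage could leave it at 0. Single markers argue against leukocytes in the libraries with higher levels. The macrophage transcripts Tyrobp and Fcer1g were at most 0.212 TPM in the transformed libraries, the B cell gene Cd79a at most 0.139 TPM and the T cell gene Cd3e at most 0.0922 TPM. Csf1r, at 11.3 to 38.7 TPM, is the exception among them, with a mean Nf1 log2 ratio of −0.99. The authors' scaling to a fixed total does not account for the pattern, since the median ratio nearest 0 over both lists and both contrasts was −0.67 under 3 rescalings. Shifts of whole chromosomes do not either, with −0.62 after centring. Centring subtracts the median of each chromosome, so a shift of part of a chromosome was not tested. Whether loss of Nf1 or another difference between the lines lies behind it cannot be told apart with 1 library per genotype, and a lower interferon output of the Nf1-labelled lines remains an untested hypothesis.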
